A study of Mus musculus with 12 samples.

How the data were processed

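RNA was sequenced in bulk from epididymal white adipose tissue (eWAT) of 12 male mice aged 12 to 14 weeks, per the labels. The strain is given as C57bl6 in the sample labels and as C57BL6/J in the series design. The groups were 4 mice after sham surgery, 5 mice at day 3 and 3 mice at day 7 after removal of 70% of the liver. Each library came from a separate animal, so the spread between libraries measures variation between animals together with preparation. The p-values of single genes rest on that spread. Per the labels' protocols, RNA was extracted from frozen tissue with QIAzol, cleaned up on RNeasy columns and treated with DNase, and libraries were made by a service provider. The labels name the molecule polyA RNA, and the series design speaks of total RNA sequencing. Strandedness is not stated, so reads of a gene and of an overlapping or antisense partner could not be separated. The labels do not state on which day the sham mice were sampled, and their source field describes them as preceding hepatectomy.

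Per the submitters' processing notes, the data were processed with Partek, STAR and DESeq2 against build mm39; versions, settings and the role of each tool are not stated. The per-sample values used for all tests are expected counts per gene, raw counts per the file headers: 29.4% to 39.8% of the values of a sample were not whole, and 80.6% of all values lay within 0.05 of a whole number. A parallel block of normalized count signal was made by the authors by dividing each sample by 1 factor, and served here only to match values to genes. Each gene also carries the authors' deposited p-value, step-up false discovery rate (FDR) and log2 ratio for day 3 and day 7 against sham. Where these are quoted, the sentence names the authors' deposited table.

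In the authors' deposited table the per-sample values do not stand beside the genes they belong to: 18086 lines of per-sample values stand beside the first of 22151 genes. Each line was therefore assigned to the gene whose deposited mean and maximum over the samples it gave, within a relative tolerance of 3e-05. The deposited geometric mean had to match as well, within a looser tolerance. Before this, the values of each sample were divided by 1 factor estimated from a first, looser matching. Of these lines, 18070 matched 1 gene, the other 16 were settled by their neighbours, and 0 broke the order of the genes. Only 21 lines stood beside their own gene, and 18065 stood beside another. After matching, the authors' group means lay within 5% of the means of the assigned values for 100% of the genes compared in each group. Genes with low normalized counts in a group were left out of that comparison. The 4065 genes with no per-sample values hold 0.0784% of the normalized counts and were not tested. Per-sample columns that belonged to no labelled sample numbered 0. Gene symbols, Ensembl identifiers and mm39 coordinates were taken as the authors' deposited table gives them; the reference annotation at hand is of another build and was not used.

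Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3, with statmod 1.5.0. Genes were kept by filterByExpr with a minimum count of 10, which left 17012, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood F-test with robust dispersion was fitted to all 12 libraries with 1 coefficient per group, and day 3 against sham, day 7 against sham and day 7 against day 3 were taken from that fit. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Levels are CPM (TMM-scaled counts relative to library size), as mean ± SD; log2 differences are edgeR estimates with their standard errors (SE). Before the data were examined, 43 gene lists of pathways and cell types were fixed, and the 40 with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 40 lists. Camera compares the members of a list with all other genes. At a preset correlation its p-value therefore does not measure how a list as a whole varies between animals. A list score is the mean over members of log2 CPM relative to each gene's mean over the 12 libraries, with a prior count of 2. Which lists are described was chosen after their results were seen.

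The rule for naming genes was also fixed before the data were examined. Adipoq, Lep, Pparg, Pnpla2, Lipe, Fasn, Ucp1, Lcn2, Il6 and Ccl2 are given for each comparison with sham. Among genes past the threshold with a mean of at least 1 CPM, groups that do not overlap and a symbol that is not a predicted model, the 6 with the largest positive and the 6 with the largest negative log2 difference are given (5 of each for day 7 against day 3). Where no gene passed, the 4 with the smallest p are given as not past the threshold. From each described list up to 4 members with the smallest adjusted p and a mean of at least 1 CPM are named, and genes that mark a library standing apart are named as well. Members that go against their list, and any other gene, were chosen after their values were seen.

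The depth of 13128832 to 23474247 counts per library, with a biological coefficient of variation of 0.541, gave a median SE of 0.357 log2 units at day 3 and 0.406 at day 7 against sham, and 0.389 between the days. The tests were tested on simulated counts with known changes, 150 changed genes per fold size over 3 simulations. For day 3 against sham (16487 genes on average), edgeR recovered 14% of genes changed 2-fold, 62.7% changed 4-fold, 80.7% changed 8-fold and 84.7% changed 16-fold, with 5 false calls on average. For day 7 against sham (16497 genes) the shares were 7.33%, 63.3%, 74.7% and 82.7%, and for day 7 against day 3 (16500 genes) 10.7%, 56.7%, 76.7% and 81.3%. DESeq2 1.42.0 made 43.7, 48.7 and 47.7 false calls on average in the same simulations, against 5, 5 and 4.67 with edgeR. Simulated genes were independent and simulated libraries held no outlying animals, so these recovered shares need not hold for the real libraries. A simulated list of 20 members shifted by 1 log2 unit passed camera in 3 of 3 simulations for each comparison, and an unshifted one in 0 of 3. Genes were simulated as independent, so this does not show how often camera passes unshifted lists of correlated genes. The estimated correlation of the real lists was higher, for example 0.863 for the cell cycle at day 3. Another split of the day 3 and sham libraries passed 24 lists.

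Alternatives tried were DESeq2 size factors and upper-quartile scaling in edgeR, no filter and a stricter filter on low counts, the DESeq2 Wald test, limma voom with quality weights, a fit to only the 2 groups compared, the replicate number as a block, a minimum absolute log2 difference of 1, and each library left out in turn. For lists, the correlation estimated per list, fry in place of camera, and lists without shared genes were tried. The overlap between days was set against 10 simulations of unchanged groups with shared controls and against sham libraries divided between the comparisons. Other splits of the libraries were tested, up to 100 per comparison.

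A few genes among those with the smallest p and among the members of the lists are not reported here; they stayed in every test and count.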

Results

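Bulk RNA sequencing measured gene expression in epididymal white adipose tissue (eWAT), a visceral fat depot beside the testis, in 12 mice. The sham group (4 mice) had the abdomen opened and the liver left whole. The other mice were sampled at day 3 (5 mice) or day 7 (3 mice) after 70% partial hepatectomy, a procedure after which the remaining liver regrows. The series title concerns hepatic Yap1, systemic catabolism and muscle loss in organ repair and in cancer cachexia. The comparisons address how a fat depot outside the liver differs from sham during regrowth, and how the days differ. Library totals were 23474247, 18452560, 16368065 and 19114214 counts in sham libraries 1 to 4. They were 14758295, 18106714, 13128832, 16376619 and 15759820 counts in day 3 libraries 1 to 5, and 15860801, 16041908 and 15229192 counts in day 7 libraries 1 to 3.

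Several libraries stood apart from their groups. Day 3 library 5 had a mean correlation of 0.926 with the sham libraries and 0.894 with its own group, and its nearest library was day 7 library 2 (0.957). Day 7 library 1 was nearest to day 3 library 2 (0.936), with a mean of 0.869 to its own group; these correlations are across genes, which are not independent replicates. Sham library 4 held 2315 CPM of Alb, the albumin transcript of hepatocytes, where the other sham libraries held at most 5.99 CPM. In day 3 library 1, Xist, the RNA that coats an inactive X chromosome, stood at 359 CPM (at most 1.84 CPM in every other library). The Y-linked gene Ddx3y stood there at 0.643 CPM (at least 81.1 CPM in every other library), although the labels say male mice. All 12 libraries entered the tests.

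At day 3 after hepatectomy, genes that respond to glucocorticoids, genes of the circadian clock and haemoglobin genes rose as groups against sham by camera with the preset correlation; with an estimated correlation they did not pass (adjusted p = 0.25, 0.261 and 0.261). Genes of the cell cycle, B cells, dendritic cells, mast cells and the interferon response fell as groups in the same way (0.642, 0.261, 0.261, 0.261 and 0.457 with an estimated correlation). The cell cycle call ended without sham library 1 (camera adjusted p = 0.0743). A single gene passed the test over all 17012 genes tested: Pttg1 (ENSMUSG00000020415), which encodes securin, the inhibitor of separase that keeps sister chromatids joined until anaphase. Pttg1 lies on chromosome 11 from 43311077 to 43317078 on the minus strand (mm39). It fell by 3.24 on the log2 scale (SE 0.388, edgeR adjusted p = 0.0253), from 32.4 ± 3.76 CPM (SD, n = 4) in sham to 3.44 ± 1.06 CPM (SD, n = 5). The 5 day 3 libraries lay between 2.43 and 5.23 CPM and the 4 sham libraries between 28.5 and 37.5 CPM. The call ended, with the log2 difference between -3.44 and -3.15, when any 1 sham or day 3 library was left out: the edgeR adjusted p was then 0.0535 to 0.204 across those 9 fits. It was 0.0576 with voom and 2.2e-11 with DESeq2. An inherited difference between the animals may lie behind the low Pttg1 and could not be told apart from an effect of hepatectomy.

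**Figure D1:**
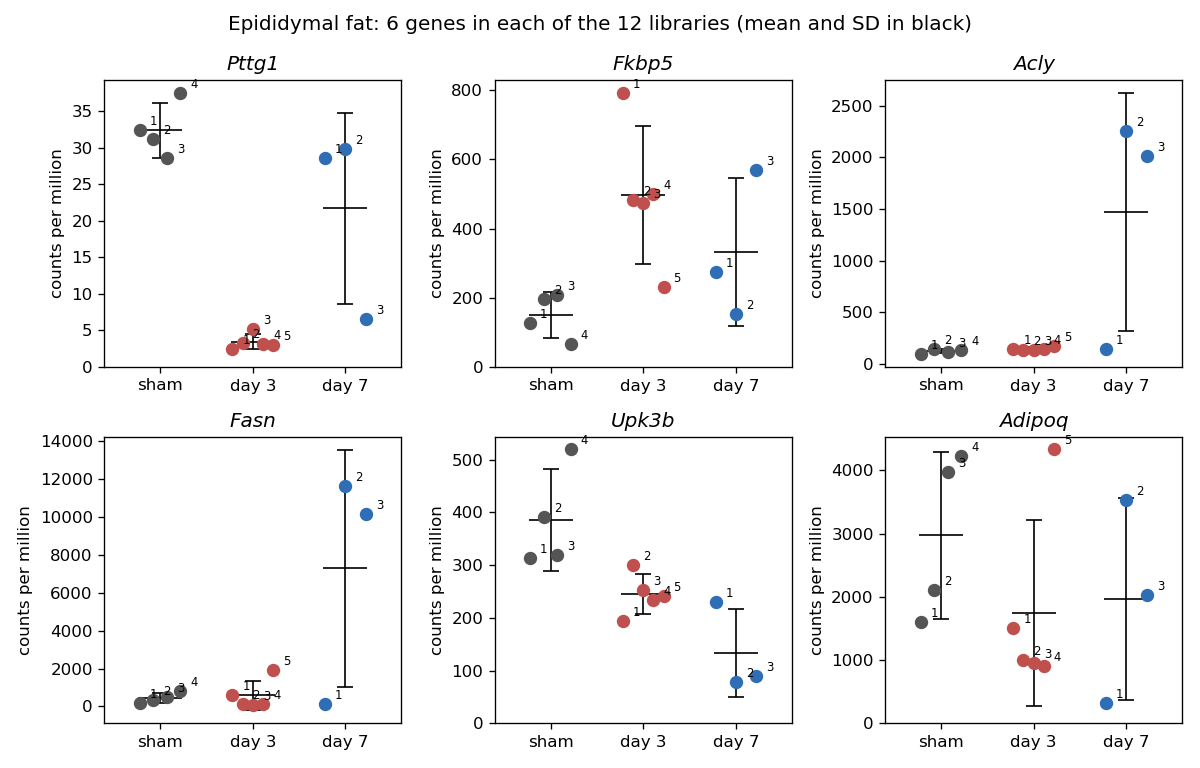
CPM (vertical axis, 1 panel per gene) of Pttg1, Fkbp5, Acly, Fasn, Upk3b and Adipoq in each of the 12 libraries; each point is 1 library, numbered by replicate, in the sham, day 3 and day 7 groups (horizontal axis), and black marks give the mean and SD. Pttg1 lies between 2.43 and 5.23 CPM in the day 3 libraries and between 28.5 and 37.5 CPM in sham, and Acly lies at 2256 and 2009 CPM in day 7 libraries 2 and 3 and at most at 176 CPM in the other libraries.

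Of 20 measured glucocorticoid response genes, 19 had positive log2 differences at day 3 (median 1.22), and the list rose (camera adjusted p = 4.8e-12; adjusted p = 0.25 with an estimated correlation). Passing members numbered 13 adjusted over the list alone and 0 over all genes tested. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 150 ± 66.4 CPM (SD, n = 4) in sham and 496 ± 199 CPM (SD, n = 5) at day 3, a log2 difference of 1.73 (SE 0.457). Klf9, a transcription factor induced by glucocorticoids, stood at 172 ± 45.4 and 400 ± 145 CPM (log2 difference 1.22, SE 0.320), and Errfi1, a feedback inhibitor of EGF receptor signalling, at 110 ± 32.7 and 375 ± 171 CPM (1.77, SE 0.454). The log2 difference of Map3k6, a stress-activated kinase, was 1.64 (SE 0.478); the edgeR adjusted p of each of these 4 genes was 0.403. The member that went the other way was Nr3c1, the receptor itself (-0.42). The list score was 0.60 to 0.92 in day 3 libraries 1 to 4, and -0.34 in library 5, inside the sham range of -1.27 to -0.12.

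Clock genes rose as a list of 18, with 15 positive members and a median of 0.62 (camera adjusted p = 2.7e-04; adjusted p = 0.261 with an estimated correlation). Cry2, a repressor of the clock, stood at 50.9 ± 12.4 CPM in sham and 100 ± 23.6 CPM at day 3 (log2 difference 0.98, SE 0.230), and the repressor Per2 at 21.7 ± 6.36 and 45.0 ± 14.9 CPM (1.06, SE 0.287). Per1 and Nfil3 had log2 differences of 1.07 and 1.86. Per3, Hlf and Dbp, an output gene of the clock, went the other way (-0.23, -0.03 and -1.39). Passing members numbered 2 adjusted over the list alone and 0 over all genes tested.

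Ubiquitin ligase and atrophy genes, which serve protein breakdown in wasting tissue, rose as a list of 17 with 14 positive members and a median of 0.41 (camera adjusted p = 0.00488; adjusted p = 0.261 with an estimated correlation). Its leading members were the activin receptor Acvr1b (log2 difference 1.33, SE 0.453), the proteasome subunits Psmb5 (0.52, SE 0.184) and Psma1 (0.38, SE 0.143), and Gdf15, a stress hormone that lowers appetite (0.701 ± 0.552 CPM in sham, 6.49 ± 5.03 CPM at day 3). Fbxo21, Ube2b and Acvr1c went the other way (-0.60, -0.06 and -0.81), and 0 members passed, both adjusted over the list alone and over all genes tested. The edgeR adjusted p of the named genes was 0.403 to 0.444.

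Red blood cell genes rose as a list of 8 with 8 positive members and a median of 2.07 (camera adjusted p = 9.8e-07; adjusted p = 0.261 with an estimated correlation), and 5 passed adjusted over the list alone and 0 over all genes tested. The haemoglobin gene Hbb-bs stood at 1138 ± 559 CPM in sham and 5371 ± 3924 CPM at day 3, and Hba-a1 at 645 ± 287 and 3349 ± 2359 CPM. Day 3 library 1 showed no rise. It held 861 CPM of Hbb-bs, inside the sham range of 595 to 1874 CPM. Its list score was -1.81, inside the sham range of -2.03 to 0.04. The log2 differences of Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt were 2.24, 2.38, 2.34 and 2.04. Hba-a1 and Hba-a2 are nearly identical paralogs, as are Hbb-bs and Hbb-bt, so the split of reads within each pair is uncertain.

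Cell cycle genes fell as a list: 37 of 38 members had negative log2 differences at day 3, with a median of -1.84 (camera adjusted p = 1.3e-07; adjusted p = 0.642 with an estimated correlation). Prc1, a bundler of the mitotic spindle midzone, stood at 30.2 ± 39.2 CPM in sham and 2.61 ± 1.07 CPM at day 3, and Kif23, a kinesin of cytokinesis, at 9.13 ± 8.46 and 1.71 ± 0.655 CPM. The log2 differences of Tyms and Cenpf were -1.29 and -2.47; the replication licensing gene Cdt1 went the other way (0.15). Members passing numbered 0 adjusted over the list alone and 0 over all genes tested. Sham library 1 carried much of the sham level, with 191 CPM of the proliferation marker Mki67 and 87.1 CPM of Prc1; without it the camera adjusted p was 0.0743.

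Lists of several immune cell types fell at day 3. B and plasma cell genes fell with 10 of 12 members negative and a median of -2.76 (camera adjusted p = 8.2e-05; adjusted p = 0.261 with an estimated correlation). The immunoglobulin light chain gene Igkc stood at 58.6 ± 38.6 CPM in sham and 7.41 ± 7.24 CPM at day 3, and the log2 differences of Ighd, Cd22 and Cd79b were -3.23, -2.08 and -3.37. Sdc1 (0.35) and Xbp1 (0.91), which other cells express too, went the other way. Dendritic cell genes fell with 10 of 12 members negative and a median of -1.26 (camera adjusted p = 1.2e-04; adjusted p = 0.261 with an estimated correlation). Cd74, the invariant chain of antigen presentation, stood at 335 ± 169 CPM in sham and 105 ± 145 CPM at day 3. Batf3, Zbtb46 and Siglech had log2 differences of -2.01, -0.49 and -2.95, against 0.61 and 0.64 for Flt3 and Fscn1. Mast cell, eosinophil and ILC2 genes fell with 9 of 11 members negative and a median of -1.60 (camera adjusted p = 0.00226; adjusted p = 0.261 with an estimated correlation). The mast cell proteases Cpa3, Cma1 and Tpsb2 had log2 differences of -1.97, -2.32 and -1.93, while Kit, the stem cell factor receptor (1.47), and Rora (0.64) went the other way. Members passing adjusted over the list alone numbered 0 for B and plasma cells, 0 for dendritic cells and 1 for mast cells, Cpa3, and 0 over all genes tested. Day 3 library 5 again lay away from its group, with a B and plasma cell score of 0.46 where the other day 3 libraries had -1.41 to -0.98.

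Interferon response genes fell at day 3, with 24 of 26 members negative and a median of -0.69 (camera adjusted p = 2.2e-06; adjusted p = 0.457 with an estimated correlation). The antiviral synthetase gene Oas2 stood at 27.1 ± 5.33 CPM in sham and 9.58 ± 4.88 CPM at day 3 (log2 difference -1.50, SE 0.399), and Irf1 and Oasl2 each had a log2 difference of -0.63. Bst2, which encodes tetherin, went the other way (41.0 ± 21.2 and 93.1 ± 20.3 CPM; log2 difference 1.18, SE 0.319), as did Cxcl10 (0.33). Adjusted over the list alone, 1 member passed upward (Bst2) and 1 downward (Oas2), and 0 over all genes tested.

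Genes of IL-6 and STAT3 signalling and the acute phase rose as a list of 26, with 21 positive and a median of 0.69 (camera adjusted p = 0.00218; adjusted p = 0.642 with an estimated correlation). Stat3, the transcription factor downstream of IL-6, stood at 190 ± 35.1 CPM in sham and 431 ± 187 CPM at day 3 (log2 difference 1.18, SE 0.405). The receptor genes Il6ra and Osmr had log2 differences of 1.00 and 0.81. The acute phase genes Orm1, Orm2 and Saa3 went the other way (-1.83, -1.33 and -0.96), as did Socs1 (-0.24) and Timp1 (-0.34). Mesothelial genes, of the cell layer that covers the fat pad, fell with 14 of 17 members negative and a median of -0.44 (camera adjusted p = 0.00850; adjusted p = 0.642 with an estimated correlation). The log2 differences of Nkain4, Gpm6a, Upk3b and Bnc1 were -0.92, -0.74, -0.66 and -0.58, and those of Msln, Krt18 and Slpi were 0.38, 0.40 and 0.28. In both lists 0 members passed, adjusted over the list alone or over all genes tested. Without sham library 4 the camera adjusted p of the IL-6 list was 0.0515, and without day 3 library 1 that of the mesothelial list was 0.0542; with both libraries left out the values were 0.204 and 0.154.

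Genes of the adipocyte itself did not pass as groups at day 3. The camera adjusted p was 0.257 for mature adipocyte genes (7 of 20 positive, median -0.33), 0.502 for lipolysis (9 of 20, median -0.07) and 0.153 for fatty acid and triglyceride synthesis (8 of 23, median -0.24). Adipoq, which encodes adiponectin, stood at 2973 ± 1318 CPM in sham and 1740 ± 1468 CPM at day 3, and Cebpa at 815 ± 180 and 437 ± 360 CPM. Cd36, a fatty acid transporter, stood at 2681 ± 519 and 3987 ± 516 CPM, Fabp4 at 9886 ± 441 and 13423 ± 3641 CPM, and the lipase gene Pnpla2 at 2969 ± 959 and 3789 ± 781 CPM. Hilpda, an inhibitor of that lipase, had a log2 difference of 2.85 (SE 1.17), and Angptl4, Prkaca and the glycerol channel Aqp7 had 0.91, -0.73 and -1.52. In fatty acid synthesis, Scd1, Pck1, Elovl5 and Srebf1 had log2 differences of 0.86, -0.72, -0.38 and -0.89. The log2 differences of the other genes named for every comparison were 0.30 for the leptin gene Lep, -0.25 for Pparg, 0.01 for the hormone-sensitive lipase gene Lipe, 0.34 for Fasn, 0.72 for Lcn2, 0.55 for Il6 and 1.80 for Ccl2, each with an edgeR adjusted p of 0.615 or more. The value for Fasn was -0.95 without day 3 library 5. With 1 library left out in turn, Il6 ran from 0.12 (without sham library 4) to 2.21 (without sham library 1) and Lep from 0.040 (without sham library 3) to 0.98 (without sham library 2). Without day 3 library 5, which held 4331 CPM of Adipoq where the others held 909 to 1502, mature adipocyte genes fell (camera adjusted p = 0.0312) and fatty acid and triglyceride synthesis genes fell (0.0119; 0.0286 without sham library 1).

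YAP and TEAD target genes, the transcriptional output of the Hippo pathway, did not pass as a list at day 3 (16 of 25 positive, median 0.15, camera adjusted p = 0.0856; 0.0379 without day 3 library 4). Ccn2, a matricellular protein and common reporter of YAP activity, stood at 23.7 ± 18.5 CPM in sham and 120 ± 93.7 CPM at day 3 (log2 difference 2.34, SE 0.723), and the partner transcription factor Tead1 at 125 ± 34.6 and 319 ± 180 CPM (1.35, SE 0.439). Igfbp3 and Nt5e had log2 differences of 2.19 and 1.22; the edgeR adjusted p of the 4 genes was 0.403 to 0.418. Liver genes did not pass at day 3 (camera adjusted p = 0.361), with log2 differences of -5.99 for Ahsg, -6.24 for Alb, -6.29 for Mup3 and -5.88 for Hpx that rested on sham library 4. Without that library the liver list rose at day 3 (camera adjusted p = 0.00162), and without sham library 1 it fell (0.00556).

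Between day 3 and sham, edgeR called 1 gene, with 1849 genes at an unadjusted p under 0.05, where chance gives 850.6 on average. Other splits of these libraries gave 170 to 3813 such genes, so the excess is not shown to be beyond chance. DESeq2 called 122 genes (77 higher and 45 lower) and voom with quality weights called 0. With sham library 4 and day 3 library 1 left out edgeR called 0 genes (adjusted p of Pttg1 = 0.675), and without day 7 library 1 it called 2. Of the 40 lists tested, 15 passed camera with the preset correlation, 0 passed with an estimated correlation and 0 passed fry, a test of whether a list's genes move one way on balance.

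At day 7, genes of fatty acid and triglyceride synthesis, cholesterol synthesis, lipid-associated macrophages and lysosomes rose as groups against sham by camera with the preset correlation, and mesothelial and interferon response genes fell; with an estimated correlation none of these 6 lists passed (adjusted p from 0.322 to 0.484). The glucocorticoid, clock and red blood cell lists rose and the cell cycle and B cell lists fell, as they had at day 3 (where the mesothelial, interferon response, lipid-associated macrophage and lysosome lists had passed in the same direction too), and did not pass with an estimated correlation either (0.322 to 0.740). The calls for fatty acid and triglyceride synthesis (camera adjusted p = 0.606), cholesterol (0.494) and the cell cycle (0.291) ended without day 7 library 2, and that for lysosomes (0.0567) without day 7 library 3. Without sham library 1 the B cell call ended (0.0799) and the cell cycle list turned direction (0.860). No gene passed the test over all genes. Those with the smallest p, none past the threshold, included Fras1, Acly and Ptges. Acly (ENSMUSG00000020917), the ATP citrate lyase that supplies acetyl-CoA for lipid synthesis, stood at 125 ± 22.3 CPM (SD, n = 4) in sham and 1471 ± 1153 CPM (SD, n = 3) at day 7 (log2 difference 3.56, SE 0.616, edgeR adjusted p = 0.307). Fras1 (ENSMUSG00000034687), a basement membrane protein, stood at 17.7 ± 4.18 and 3.86 ± 0.757 CPM (-2.20, SE 0.331, edgeR adjusted p = 0.284). Ptges (ENSMUSG00000050737), a prostaglandin E synthase, stood at 34.5 ± 12.2 and 159 ± 65.6 CPM (2.20, SE 0.392, edgeR adjusted p = 0.307).

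Fatty acid and triglyceride synthesis genes rose with 20 of 23 members positive and a median of 1.23 (camera adjusted p = 4.8e-05; adjusted p = 0.484 with an estimated correlation). Fasn, the fatty acid synthase, stood at 462 ± 269 CPM in sham and 7297 ± 6261 CPM at day 7 (log2 difference 3.98, SE 1.30). Gpd1, which makes the glycerol backbone of triglyceride, stood at 602 ± 116 and 1678 ± 699 CPM (1.48, SE 0.392), and the elongase Elovl6 had a log2 difference of 2.32 (SE 0.550). Pck1, the key enzyme of glyceroneogenesis, stood at 3255 ± 1466 and 945 ± 761 CPM (-1.78, SE 0.548); Lpin1 (-0.16) and Elovl5 (-0.09) also went the other way. Adjusted over the list alone, 6 members passed upward and 1 downward, and 0 over all genes tested. These genes divided the day 7 mice: Acly stood at 147, 2256 and 2009 CPM and Fasn at 115, 11608 and 10167 CPM in libraries 1, 2 and 3. The list score was -1.58 in library 1, the lowest of all 12, against 2.06 and 1.44. Without day 7 library 2 the camera adjusted p was 0.606.

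Cholesterol synthesis and uptake genes rose with 15 of 20 members positive and a median of 0.46 (camera adjusted p = 5.4e-04; adjusted p = 0.322 with an estimated correlation). The lanosterol demethylase gene Cyp51 stood at 26.5 ± 4.18 CPM in sham and 73.3 ± 36.3 CPM at day 7. Nsdhl and Lss had log2 differences of 1.42 and 0.86. Genes that went the other way included Hmgcs1, Fdft1, Dhcr7 and Stard4 (-0.52, -0.09, -0.05 and -0.03). Oxidative phosphorylation genes rose by a small amount, with 39 of 43 positive and a median of 0.24 (camera adjusted p = 0.00177; adjusted p = 0.747 with an estimated correlation). Cycs, the electron carrier cytochrome c, stood at 90.6 ± 14.8 and 133 ± 9.52 CPM. Cox7b, Uqcrq and Cyc1 had log2 differences of 0.58, 0.52 and 0.58, against -0.23, -0.22, -0.07 and -0.09 for Ndufa2, Ndufc1, Atp5h and Atp5g1. Adjusted over the list alone, 1 cholesterol gene and 0 oxidative phosphorylation genes passed, and 0 over all genes tested. Without day 7 library 2 the camera adjusted p was 0.494 for cholesterol and 0.941, with the direction turned, for oxidative phosphorylation, which also had 0.219 without sham library 2 and 0.0953 without day 7 library 3.

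Mesothelial genes fell with 16 of 17 members negative and a median of -1.14 (camera adjusted p = 3.1e-15; adjusted p = 0.322 with an estimated correlation), and 8 passed downward adjusted over the list alone, with 0 over all genes tested. Upk3b, a membrane protein of mesothelial cells, stood at 386 ± 96.6 CPM in sham and 133 ± 83.8 CPM at day 7 (log2 difference -1.54, SE 0.360). Nkain4, Gpm6a and the transcription factor Bnc1 had log2 differences of -1.37, -1.14 and -1.37. The keratin gene Krt18 went the other way (0.17). Upk3b measured 229, 78.9 and 90.4 CPM in day 7 libraries 1, 2 and 3, all below the lowest sham library (313 CPM). The list score was 0.27, -1.27 and -1.09, so the fall of the list as a whole lay in the same libraries as the high Acly and Fasn.

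Lipid-associated macrophage genes rose with 14 of 15 members positive and a median of 1.40 (camera adjusted p = 1.8e-06; adjusted p = 0.322 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden phagocytes, stood at 55.7 ± 21.2 CPM in sham and 379 ± 373 CPM at day 7 (log2 difference 2.77, SE 0.720), and Atp6v0d2, a lysosomal proton pump subunit, at 4.18 ± 1.58 and 46.4 ± 64.3 CPM (3.47, SE 1.03). The macrophage elastase gene Mmp12 and the lipid droplet coat gene Plin2 had log2 differences of 3.26 and 1.89; Fabp5 went the other way (-0.23). Autophagy and lysosome genes rose with 23 of 28 positive and a median of 0.31 (camera adjusted p = 2.3e-04; adjusted p = 0.328 with an estimated correlation; camera adjusted p = 0.0567 without day 7 library 3). The protease gene Ctsk, the pump subunit gene Atp6v1a and the lysosomal lipase gene Lipa had log2 differences of 1.71, 0.85 and 1.43, against -0.44, -0.38, -0.20, -0.17 and -0.01 for Npc2, Map1lc3a, Gabarapl1, Map1lc3b and Ctsz. Adjusted over the list alone, 7 macrophage and 3 lysosome genes passed, and 0 over all genes tested. The macrophage score was 0.89, -0.49 and 1.73 in day 7 libraries 1, 2 and 3.

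Glucocorticoid response genes rose at day 7 with 17 of 20 positive and a median of 0.72 (camera adjusted p = 2.3e-04; adjusted p = 0.322 with an estimated correlation). Fkbp5 stood at 332 ± 214 CPM and Klf9 at 295 ± 111 CPM at day 7 (log2 differences from sham 1.15 and 0.78). The log2 differences of the glutamine synthetase gene Glul and the cell cycle inhibitor gene Cdkn1a were 0.76 and 1.64. Nr3c1, Lpin1 and Klf15 went the other way (-0.17, -0.16 and -0.08). Without day 7 library 1 the value for Cdkn1a was -0.10. The list score was 0.44, -0.51 and -0.14 in day 7 libraries 1, 2 and 3, the last 2 inside the sham range of -1.27 to -0.12; without library 1 the list still passed (camera adjusted p = 0.0170). Clock genes rose with 16 of 18 positive and a median of 0.41 (camera adjusted p = 0.00102; adjusted p = 0.322 with an estimated correlation). Bhlhe40, Nfil3, Cry2 and Arntl had log2 differences of 1.55, 2.08, 0.44 and 0.65, against -0.43 for Npas2 and -0.24 for Hlf. Hypoxia and glycolysis genes rose with 17 of 24 positive and a median of 0.49 (camera adjusted p = 4.7e-04; adjusted p = 0.322 with an estimated correlation). The glycolytic genes Aldoa and Ldha stood at 800 ± 173 and 617 ± 146 CPM in sham and 1477 ± 308 and 1064 ± 172 CPM at day 7. The glucose transporter gene Slc2a1 and the hexokinase gene Hk2 had log2 differences of 2.97 and 0.68. Members that went the other way included P4ha1, Egln3, Adm and Car9 (-0.70, -0.68, -0.47 and -0.33), all targets of hypoxia signalling. In these 3 lists 0 members passed, adjusted over the list alone or over all genes tested.

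Interferon response genes fell at day 7 with 23 of 26 negative and a median of -0.37 (camera adjusted p = 4.8e-05; adjusted p = 0.363 with an estimated correlation). The list score was -0.67, 0.28 and 0.11 in day 7 libraries 1, 2 and 3, the last 2 inside the sham range of -0.14 to 0.78. Oasl2, Oas2, Cxcl9 and Isg15 had log2 differences of -0.99, -1.48, -1.53 and -1.06, with genes that went the other way including Cxcl10 and Rsad2 (0.24 and 0.16); 1 gene, Oasl2, passed adjusted over the list alone and 0 over all genes tested. Red blood cell genes rose with 8 of 8 positive and a median of 1.36 (camera adjusted p = 4.8e-05; adjusted p = 0.322 with an estimated correlation). The membrane anion exchanger gene Slc4a1 had a log2 difference of 2.29, and Hba-a1, Hba-a2 and Hbb-bt had 1.6, 1.39 and 1.27. Hbb-bs measured 5134, 1608 and 1471 CPM in day 7 libraries 1, 2 and 3, the last 2 inside the sham range of 595 to 1874 CPM. The list score was 0.84, 0.31 and -0.04 in these libraries, against -2.03 to 0.04 in sham. Cell cycle genes fell with 36 of 38 negative and a median of -0.99 (camera adjusted p = 3.1e-04; adjusted p = 0.740 with an estimated correlation). Cenpf, Mcm7, Mcm4 and Tyms had log2 differences of -2.18, -0.55, -0.75 and -0.84, against 0.40 and 0.23 for Cdt1 and Pcna. B and plasma cell genes fell with 9 of 12 negative and a median of -2.29 (camera adjusted p = 0.00632; adjusted p = 0.322 with an estimated correlation). Ighd, Cd79a and Igkc had log2 differences of -3.64, -4.48 and -2.24, against 0.91, 0.52 and 0.32 for Sdc1, Xbp1 and Ighm. In these last 3 lists 0 members passed, adjusted over the list alone or over all genes tested. Without sham library 1 the camera adjusted p was 0.860, with the direction turned, for the cell cycle and 0.0799 for B and plasma cells; without day 7 library 2 it was 0.291 for the cell cycle.

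Mature adipocyte genes fell at day 7 by a small amount, with 15 of 20 negative and a median of -0.25 (camera adjusted p = 0.0452; adjusted p = 0.700 with an estimated correlation). Trarg1, a regulator of glucose transporter trafficking, stood at 354 ± 56.4 CPM in sham and 170 ± 51.7 CPM at day 7. Gpd1, Slc2a4, Cd36, Retn and Cfd went the other way (1.48, 0.23, 0.21, 0.21 and 0.14). Of the members, Gpd1 alone passed adjusted over the list alone, with 0 over all genes tested. This call ended without sham library 3 (camera adjusted p = 0.218), sham library 4 (0.117), day 3 library 2 (0.0511) or day 3 library 3 (0.0585), and turned direction without day 7 library 1 (0.470), whose list score of -1.53 was the lowest of all. Lipolysis genes fell with 17 of 20 negative and a median of -0.25 (camera adjusted p = 0.0245; adjusted p = 0.426 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes tested. The natriuretic peptide receptor genes Npr3 and Npr1 had log2 differences of -1.09 and -0.44, against 3.30, 0.50 and 0.40 for Hilpda, G0s2 and Abhd5; without day 7 library 1 the value for Hilpda was -0.16. The lipolysis call ended without sham library 2 (camera adjusted p = 0.0718), sham library 3 (0.0973), day 7 library 1 (0.385) or day 7 library 3 (0.0555), and without the genes shared with other lists (0.115).

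Thermogenic genes rose at day 7 with 11 of 20 positive and a median of 0.13 (camera adjusted p = 0.0481; adjusted p = 0.322 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes tested. The members with the smallest p were expressed at low levels. Elovl3, an elongase of brown fat, stood at 0.0647 ± 0.129 CPM in sham and 1.63 ± 1.02 CPM at day 7, Cidea at 0.902 ± 0.927 and 3.93 ± 3.62 CPM. The hormone gene Fgf21 stood at 0 CPM in the sham libraries and 4.94 ± 8.06 CPM at day 7, for which no fold is given. Gk, the glycerol kinase gene, had a log2 difference of 0.70, and Slc27a2, Fabp3, Ckmt1 and Cox7a1 were among the 9 that went the other way (-3.13, -1.61, -1.26 and -1.19). Ucp1, the uncoupling protein of brown fat, has no per-sample values here; in the authors' deposited table its log2 ratio was 2.60 at day 3 (FDR 0.788) and 2.60 at day 7 (FDR 0.984). The thermogenic call ended with DESeq2 size factors (camera adjusted p = 0.0524), without shared genes (0.0729) and without sham library 1 (0.304), sham library 2 (0.0907), day 3 library 1 (0.0653), day 3 library 2 (0.0511), day 3 library 4 (0.0576), day 7 library 2 (0.304) or day 7 library 3 (0.0772).

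YAP and TEAD targets did not pass at day 7 (11 of 25 positive, camera adjusted p = 0.810). Their median was -0.06, their mean 0.19 and the test's direction downward, and the direction turned without day 7 library 2 (0.941) or day 7 library 3 (0.525). Ccn2 stood at 79.5 ± 45.1 CPM at day 7 (log2 difference 1.75, SE 0.765). Fjx1, Rbms3 and Crim1 had log2 differences of 1.76, -0.71 and -0.41. Of the genes named for every comparison, Adipoq had a log2 difference of -0.60, Lep -0.77, Pparg -0.08, Pnpla2 -0.22, Lipe -0.41, Lcn2 0.34, Il6 1.90 and Ccl2 1.31, each with an edgeR adjusted p of 0.881 or more; for Fasn it was 0.719. Without day 7 library 1 the log2 differences of Fjx1, Pparg, Lcn2 and Il6 were -0.22, 0.30, -2.05 and -2.38. Liver genes did not pass at day 7 (camera adjusted p = 0.995), with log2 differences of -4.83 for Mup3, -3.54 for Apob, -3.0 for Alb and -2.48 for Serpina1b that rested on sham library 4. Without that library the liver list rose (camera adjusted p = 4.5e-08), with levels uneven among the day 7 mice: Alb measured 24.6, 192 and 1.58 CPM, Ahsg 5.55, 35.4 and 0.984 CPM and Hpx 11.6, 30.5 and 0.328 CPM in day 7 libraries 1, 2 and 3; its direction also turned without day 3 library 3 (0.997) or day 7 library 3 (0.195).

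In all, 12 lists passed camera in the same direction at both days. Their calls include lipid-associated macrophages (camera adjusted p = 0.0340) and lysosomes (0.0243) upward at day 3, and dendritic cells (0.0165) and mast cells (0.0153) downward and immediate early genes (0.00804) upward at day 7. With an estimated correlation the adjusted p of these 5 was 0.642, 0.642, 0.363, 0.322 and 0.700. The macrophage call at day 3 ended without sham library 3 (camera adjusted p = 0.0700) or 4 (0.105) or day 3 library 2 (0.0597), 3 (0.188) or 4 (0.0750), and the lysosome call without day 3 library 3 (0.0633) or with sham library 4 and day 3 library 1 both left out (0.0732). At day 7 the dendritic cell call ended without sham library 1 (0.0504) or day 7 library 1 (0.264), and the mast cell call without day 7 library 1 (0.0823) or 3 (0.0772). The immediate early call ended without sham library 2 (0.0942) or 4 (0.103) and turned without day 7 library 1 (0.287). Without the genes shared with other lists the macrophage (0.244) and lysosome (0.0820) calls at day 3 ended.

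Against sham at day 7, edgeR called 0 genes (smallest adjusted p = 0.284), with 1065 genes at an unadjusted p under 0.05 and 850.6 given by chance on average. Other splits of these libraries gave 299 to 2253 such genes. DESeq2 called 70 genes (35 higher and 35 lower), voom with quality weights called 15 (6 higher and 9 lower), and edgeR without day 7 library 1 called 3. Of the 40 lists, 22 passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry.

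**Figure D2:**
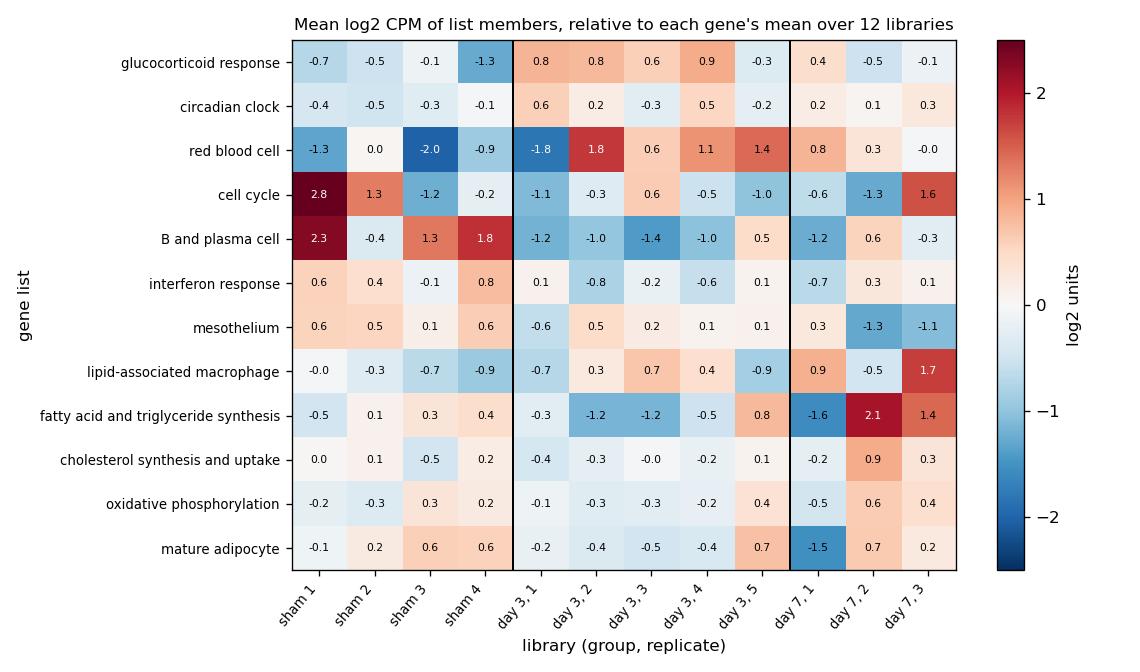
Heat map of list scores for 12 gene lists (vertical axis) in the 12 libraries (horizontal axis, grouped as sham, day 3 and day 7); colour gives the mean over list members of log2 CPM relative to each gene's mean, in log2 units. The glucocorticoid response score is 0.60 to 0.92 in day 3 libraries 1 to 4 and -0.34 in day 3 library 5, and the fatty acid and triglyceride synthesis score is -1.58, 2.06 and 1.44 in day 7 libraries 1, 2 and 3.

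Between the days, lipid synthesis and oxidative phosphorylation genes rose from day 3 to day 7, and mesothelial, glucocorticoid response, matrix, and YAP and TEAD target genes fell, by camera with the preset correlation. With an estimated correlation none of these lists passed (adjusted p from 0.315 to 0.638). The calls for cholesterol (camera adjusted p = 0.0872) and oxidative phosphorylation (0.248) ended without day 7 library 2, and that for YAP and TEAD targets without day 3 library 2 (0.0560), day 7 library 2 (0.0588) or day 7 library 3 (0.190). No gene passed over all genes. The 4 genes with the smallest p, none past the threshold, were Pttg1, Acly, Fras1 and Ptges. Pttg1 stood at 3.44 ± 1.06 CPM (SD, n = 5) at day 3 and 21.7 ± 13.1 CPM (SD, n = 3) at day 7 (log2 difference 2.66, SE 0.4, edgeR adjusted p = 0.279). The log2 differences of Acly, Fras1 and Ptges were 3.32 (SE 0.563), -1.80 (SE 0.318) and 1.93 (SE 0.364), with edgeR adjusted p-values of 0.437, 0.437 and 0.479. Pttg1 measured 28.6 and 29.9 CPM in day 7 libraries 1 and 2, inside the sham range, and 6.56 CPM in library 3.

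Fatty acid and triglyceride synthesis genes rose from day 3 to day 7 with 20 of 23 positive and a median of 1.40 (camera adjusted p = 2.8e-13; adjusted p = 0.350 with an estimated correlation). Of the members, 11 passed upward adjusted over the list alone and 0 over all genes tested. Elovl6, Acaca, which encodes acetyl-CoA carboxylase, and Gpd1 had log2 differences of 2.63, 1.94 and 1.40, against -1.06, -0.41 and -0.33 for Pck1, Scd1 and Lpin1. Cholesterol genes rose with 19 of 20 positive and a median of 0.61 (camera adjusted p = 3.9e-06; adjusted p = 0.316 with an estimated correlation), led by Mvd, Nsdhl, Dhcr7 and Fdps (1.04, 1.09, 0.93 and 0.83) and with Hmgcs1 at -0.08. Oxidative phosphorylation genes rose with 43 of 43 positive and a median of 0.34 (camera adjusted p = 1.8e-07; adjusted p = 0.638 with an estimated correlation), led by Cycs, Uqcrq, Cox5a and Ndufs1 (0.50, 0.66, 0.42 and 0.76). In the last 2 lists 0 members passed, adjusted over the list alone or over all genes tested. Without day 7 library 2 the camera adjusted p was 0.0872 for cholesterol and 0.248 for oxidative phosphorylation.

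Mesothelial genes fell from day 3 to day 7 with 17 of 17 negative and a median of -0.53 (camera adjusted p = 2.0e-09; adjusted p = 0.315 with an estimated correlation). Upk3b, Cldn15, Wt1 and Bnc1 had log2 differences of -0.88, -0.99, -0.88 and -0.79. Glucocorticoid response genes fell with 18 of 20 negative and a median of -0.48 (camera adjusted p = 1.3e-05; adjusted p = 0.340 with an estimated correlation). Sgk1, a kinase induced by corticosteroids, stood at 228 ± 69.1 CPM at day 3 and 127 ± 92.6 CPM at day 7. Map3k6, Tsc22d3 and Errfi1 had log2 differences of -1.0, -0.59 and -0.74, against 0.25 and 0.13 for Nr3c1 and Glul. Collagen and extracellular matrix genes fell with 31 of 36 negative and a median of -0.44 (camera adjusted p = 1.3e-05; adjusted p = 0.481 with an estimated correlation). Thbs2, a matricellular thrombospondin, stood at 625 ± 357 CPM at day 3 and 179 ± 195 CPM at day 7. Col6a1, Sparc and Timp3 had log2 differences of -0.60, -0.71 and -0.47, against 0.64, 0.47, 0.29, 0.04 and 0.02 for Lum, Col8a1, Col15a1, Serpinh1 and Acta2. YAP and TEAD targets fell with 17 of 25 negative and a median of -0.26 (camera adjusted p = 0.00670; adjusted p = 0.315 with an estimated correlation). Tead1 stood at 319 ± 180 CPM at day 3 and 124 ± 61.4 CPM at day 7. Amotl2, Wwtr1, which encodes TAZ, and Crim1 had log2 differences of -0.86, -0.48 and -0.32. Ptpn14 and Myof were among the 8 that went the other way (0.33 and 0.30). In these 4 lists 0 members passed, adjusted over the list alone or over all genes tested. The call for YAP and TEAD targets ended without day 3 library 2 (camera adjusted p = 0.0560), day 7 library 2 (0.0588) or day 7 library 3 (0.190).

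From day 3 to day 7, edgeR called 0 genes (smallest adjusted p = 0.279), with 568 at an unadjusted p under 0.05 where chance gives 850.6 on average. Other splits of these libraries gave 137 to 4585 such genes. DESeq2 called 22 (16 higher and 6 lower) and voom with quality weights 2 (2 higher and 0 lower). Without day 7 library 1 edgeR called 4 genes, and without day 7 library 3 it called 1. Of the 40 lists, 14 passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry.

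The day 3 and day 7 differences from sham ran in the same direction for 75.8% of genes (Pearson correlation across genes 0.684, covariance 0.476). Unchanged groups simulated with shared simulated controls gave 66.2%, and division of the sham libraries 2 and 2 gave 61.6%. The same simulation gave a correlation of 0.476 and a covariance of 0.230, a difference in covariance of 0.246. It drew all 12 libraries anew from the mean sham levels, each gene independently. It therefore lacked the outlying sham libraries and the correlation between genes, and is not a baseline for these 4 sham libraries. With the sham libraries divided 2 and 2 between the comparisons, the mean of 6 divisions was a correlation of 0.241 and a covariance of 0.203 with no sham library in common; unchanged groups were not simulated for that division. edgeR called 0 genes at both days. DESeq2, which called 77 higher and 45 lower genes at day 3 and 35 and 35 at day 7, called 6 as higher at both (0.158 expected from independent lists) and 7 as lower at both (0.0926 expected). Part of that excess may come from the shared sham libraries.

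The authors' deposited table lists 124 genes at an FDR under 0.05 at day 3 (66 higher and 58 lower), of which 101 have per-sample values, and 2379 at an unadjusted p under 0.05. At day 7 the authors' deposited table lists 50 genes (30 higher and 20 lower) and 1393 at an unadjusted p under 0.05. In the authors' deposited table, 9 genes were higher at both days (0.0900 expected from independent lists) and 4 lower at both (0.0528 expected). For Pttg1 at day 3 the authors' deposited table gives a log2 ratio of -3.24 with an FDR of 1.3e-11, and for Acly at day 7 a log2 ratio of 3.58 with an FDR of 2.7e-06. Of the 37 genes that the authors' deposited table lists as lower at day 3 and that have per-sample values, 4 stood in sham library 4 at more than 5 times every other sham library. The other 21 of the 58 lower genes have no per-sample values and include genes expressed in liver, such as Ces1c, Cyp3a25 and Ambp (FDR 4.1e-47, 5.9e-07 and 2.2e-06 in the authors' deposited table), so their place in sham library 4 could not be tested.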

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

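The tests of explanations in this part, for day 3 library 5, day 7 library 1 and sham library 4, were chosen only after the results were seen; the comparisons of lists between the days were planned. A library far from the rest of its group was looked for in 90 groups of libraries, by a rule whose critical value is set to mark about 1 group in 20 by chance.

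Day 3 library 5 stood far above the other day 3 libraries for Adipoq (4331 CPM) and Fasn (1939 CPM), and its list scores were apart as well, with -0.34 for the glucocorticoid response, 0.46 for B and plasma cells, 0.74 for mature adipocytes, 0.37 for oxidative phosphorylation and -0.42 for autophagy and lysosome. Exchanged labels of this library and day 7 library 1 stay open, because 2 sets of genes, each chosen without both libraries, disagree. On 13 genes that set day 7 libraries 2 and 3 apart, on a scale from the other libraries (0) to those day 7 libraries (1), day 3 library 5 lay at a median of 0.258 (quartiles 0.179 and 0.375), where an exchange would put it near 1, and day 7 library 1 at 0.0248, as an exchange would have it. On 275 genes that set day 3 libraries 1 to 4 apart (1, the other libraries 0), day 7 library 1 lay at 1.30 (quartiles 1.02 and 1.57) and day 3 library 5 at -0.137 (quartiles -0.259 and 0.0562), both as an exchange would have it. The exchanged grouping is also the split of the day 3 and day 7 libraries with 1878 genes called, where the labelled one gave 0. As labelled, Pttg1 measured 3.05 CPM in day 3 library 5 and 28.6 CPM in day 7 library 1, and the Ndufs5 and Mid1 pairs put the first on the day 3 side and the second on the sham side (Pisd put both on the day 3 side), but an inherited difference between the animals may lie behind these. A larger share of adipocytes alone, with the other cell types in unchanged proportions, would lower the genes of those types together. Of 15 such lists 4 lay higher than in the other day 3 libraries by more than 2 SE over members, among them dendritic cells (1.89) and B and plasma cells (1.61). Another 3 lay lower, among them neutrophils (-3.72). A larger share with a changed mix of other cells could give these values too, and members of a list in 1 library are not replicates. The test therefore does not decide on the share of adipocytes. A sham mouse under a day 3 label stays open too: on pairs chosen without this library, 3 of 3 gene to pseudogene ratios lay on the day 3 side, but the same doubt holds for those pairs, and on the 275 genes it lay at the sham level. A milder response of that mouse stays open as a biological difference, untested; a day 7 mouse that responded like day 3 library 2 stays open in the same way for day 7 library 1.

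Sham library 4 stood far above the other sham libraries for Alb (2315 CPM) and Mup3 (241 CPM). RNA carried over from liver is a candidate explanation: 84.6% of the liver list, 11 of 13 measured genes, lay above 10 times the highest other sham library there, among them Fga, Fgb and Apob. The exceptions were Cyp2e1, at 8353 CPM and 11323 CPM in sham libraries 4 and 3, which fat expresses at a high level in every library, and Apoc3. No biological explanation was tested, and whether the RNA came from tissue or from handling of libraries was not tested either.

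Day 3 library 1 stood apart from the other day 3 libraries with Xist at 359 CPM, Ddx3y at 0.643 CPM and Eif2s3y at 0.715 CPM. The Y-linked gene Kdm5d stood there at 0 CPM, against at least 11.4 CPM in every other library. The Y-linked gene Uty was lowest there too. These values argue against the male label for this library. The labelled depot, which lies beside the testis, is then in doubt for it as well. How RNA without Y-linked expression came under this label was not tested.

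The day 3 and day 7 differences from sham differed from each other, by the camera test of day 7 against day 3, for 14 lists. The adjusted p was 2.8e-13 for fatty acid and triglyceride synthesis, 3.9e-06 for cholesterol, 1.8e-07 for oxidative phosphorylation and 0.00670, downward, for YAP and TEAD targets. It was 1.3e-05 for the glucocorticoid response, 1.3e-05 for collagen and matrix and 2.0e-09 for mesothelium, all downward. With an estimated correlation these 7 did not pass (adjusted p = 0.350, 0.316, 0.638, 0.315, 0.340, 0.481 and 0.315 in that order). The calls for cholesterol (camera adjusted p = 0.0872), oxidative phosphorylation (0.248) and YAP and TEAD targets (0.0588) ended without day 7 library 2, the last also without day 3 library 2 (0.0560) or day 7 library 3 (0.190). Lists that the report does not give for this comparison rose with an adjusted p of 0.0234 for the cell cycle, 0.0219 for hypoxia and glycolysis, 0.00418 for lipid-associated macrophages, 0.0272 for T and NK cells and 0.0421 for liver. Adipose progenitors and fibroblasts (0.0383) and endothelial cells (0.00673) fell. For these other 7 the adjusted p was 0.779, 0.637, 0.637, 0.315, 0.679, 0.315 and 0.638 with an estimated correlation.

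Each of these other 7 calls between the days ended without 1 of several libraries. The cell cycle call ended without day 3 library 1 (camera adjusted p = 0.168), 4 (0.0740) or 5 (0.363) and turned downward without day 7 library 3 (0.00143). The hypoxia and glycolysis call ended without day 3 library 1 (0.115), 4 (0.0849) or 5 (0.172) or day 7 library 1 (0.244), and the lipid-associated macrophage call without day 3 library 5 (0.179) or day 7 library 1 (0.112) or 3 (0.799). The T and NK cell call ended without sham library 1 (0.0860), 3 (0.0562) or 4 (0.273), day 3 library 1 (0.0548) or 4 (0.0624) or day 7 library 2 (0.113). The liver call ended without day 3 library 1 (0.0655), 2 (0.0603), 4 (0.111) or 5 (0.262) or day 7 library 1 (0.258), and turned without day 7 library 2 (0.869). The progenitor and fibroblast call ended without day 3 library 1 (0.117), 2 (0.0603) or 3 (0.0751) or day 7 library 1 (0.122) or 2 (0.0588), and the endothelial call without day 3 library 2 (0.0603), 3 (0.0582) or 4 (0.0510) or day 7 library 3 (0.694). With the replicate number as a block the cell cycle list turned downward (0.777) and the calls for hypoxia and glycolysis (0.473) and lipid-associated macrophages (0.130) ended, and with DESeq2 size factors the liver call ended (0.0514). With sham library 4 and day 3 library 1 left out, the calls for the cell cycle (0.132), hypoxia and glycolysis (0.125), T and NK cells (0.297) and progenitors and fibroblasts (0.128) ended.

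Genes with no per-sample values stood above sham in the authors' deposited table, 2 at day 3 and 3 at day 7, chosen after their values were seen. In the authors' deposited table Cldn22 has an FDR of 0.00110 at day 3 and 0.00436 at day 7, 4833427F10Rik has 1.4e-07 and 9.5e-06, and Mmp13 has 0.0298 at day 7; these differences could not be tested per library here. Below sham in the authors' deposited table stood 21 such genes at day 3 and 0 at day 7, among them the liver-expressed genes Ces1c (FDR 4.1e-47) and Cyp3a25 (FDR 5.9e-07).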

How the results depend on the processing

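Alternatives that apply only to normalized values (other pseudocounts, quantile normalization) were not run, since the values are counts. Leaving out sham library 4 with day 3 library 1, the list tests under other scalings, and DESeq2 for the overlap were chosen after seeing the data; the other alternatives were planned. The median log2 difference of all genes lay within 0.1 of 0 under every setting (furthest -0.0761, upper-quartile scaling at day 3, where it had been -0.0204). In simulations at this depth and group size, edgeR recovered 14% of genes changed 2-fold and 62.7% of genes changed 4-fold at day 3. Those simulations held no outlying libraries, so these shares need not hold for the real ones. The cause of a moved or reversed value was not tested unless a library is named below. Leaving 1 library out of the fit also leaves fewer animals to estimate the spread.

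Counts of genes were 122, 70 and 22 with DESeq2 for day 3, day 7 and day 7 against day 3, and 0, 15 and 2 with voom and quality weights, against 1, 0 and 0 with edgeR; with sham library 4 and day 3 library 1 left out edgeR called 0 at day 3. The overlap of calls was 13 genes with DESeq2, and 0 with edgeR, with the minimum log2 difference of 1 and with the sham libraries divided 2 and 2; it was not counted under the other settings. The other scalings, filters, the fit to 2 groups and the minimum log2 difference of 1 gave 1, 0 and 0. With each library left out in turn, counts ran from 0 to 2 at day 3, 0 to 3 at day 7 and 0 to 4 between the days, the highest each time without day 7 library 1. Counts of lists were 15, 22 and 14 with camera; 0, 0 and 0 with an estimated correlation; and 0, 0 and 0 with fry. With sham library 4 and day 3 library 1 left out they were 13, 22 and 11. Among described lists under settings other than 1 library left out (the pair of libraries left out together included), 212 results kept direction and side of the threshold, 78 lost the call, 3 gained it and 6 turned; with 1 library left out, 471 kept both, 30 lost, 5 gained and 10 turned. Among named genes the same counts were 1613, 3, 40 and 31, and with 1 library left out 2267, 9, 6 and 22.

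The replicate number as a block called 0 genes at day 3 and 23 lists where the fit without it called 15 (26 against 22 at day 7 and 20 against 14 between the days). The edgeR adjusted p of Pttg1 was 0.141 with the block. The numbers do not pair the animals: the 10 pairs of libraries with the same number had correlations of deviations from -0.371 to 0.187 (mean -0.0614, against 0.0162 for other numbers), with 2 above 0.1. With the block the liver list turned at day 3 (adjusted p = 0.456) and day 7 (0.00304), as did log2 differences at day 3 of Lipe (-0.049), Fasn (-0.82), Alb (0.39) and Mup3 (0.39), and at day 7 of Lcn2 (-0.22), Mup3 (1.39), Apob (3.69), Alb (2.81) and Serpina1b (3.05). With the block, 3 lists that had not passed at day 3 did: mature adipocyte (0.0182), fatty acid and triglyceride synthesis (0.0156) and YAP and TEAD targets (0.0273).

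Other values turned sign. For the liver list at day 7 the adjusted p was 0.841 with upper-quartile scaling and 0.998 with fry. With sham library 4 and day 3 library 1 left out, the liver list turned at day 3 (0.00173) and day 7 (1.1e-07), with log2 differences at day 3 of 0.056 for Ahsg, 1.05 for Alb, 0.66 for Mup3, 0.33 for Hpx, -0.16 for Lipe and -0.0090 for Il6, and at day 7 of 2.67 for Mup3, 5.52 for Apob, 4.42 for Alb, 3.5 for Serpina1b, 0.087 for Pparg and -0.046 for Lcn2; the liver genes turned because sham library 4 holds nearly all sham counts of them. Lipe at day 3, close to 0 throughout, was -0.050 with upper-quartile scaling, -0.0058 with no filter, -0.021 with the stricter filter, -0.0050 with 2 groups and -0.20 with voom. With voom, Lep (-0.27) and Fasn (-1.07) turned at day 3, and Pparg (0.054), Lcn2 (-0.46) and Il6 (-0.88) at day 7. Il6 at day 3 was 2.26 with the block and 2.88 with voom, where it had been 0.55.

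With 1 library left out in turn, the adjusted p at day 3 ran from 0.00162 to 0.703 for liver. At day 7 it ran from 4.5e-08 to 0.997 for liver, 1.5e-17 to 0.941 for oxidative phosphorylation, 4.2e-13 to 0.860 for the cell cycle, 8.6e-04 to 0.470 for mature adipocyte, 0.117 to 0.941 for YAP and TEAD targets and 3.5e-06 to 0.860 for the unfolded protein and integrated stress response. Log2 differences at day 3 ran from -0.19 to 0.13 for Lipe, -0.95 to 0.78 for Fasn, -6.65 to 1.11 for Alb, -6.83 to 1.17 for Mup3 and -6.76 to 0.20 for Hpx. At day 7 they ran from -0.30 to 0.30 for Pparg, -2.05 to 0.93 for Lcn2, -2.38 to 3.56 for Il6, -0.10 to 2.11 for Cdkn1a, -0.16 to 3.86 for Hilpda, -0.22 to 2.22 for Fjx1, -0.23 to 1.47 for Atf4, -6.71 to 2.67 for Mup3, -6.22 to 5.51 for Apob, -5.48 to 4.42 for Alb and -4.20 to 3.49 for Serpina1b. Without sham library 4, Alb, Mup3 and Hpx turned at day 3 (Ahsg went to -0.019, its sign kept), as did Mup3, Apob, Alb, Serpina1b, Pparg and Lcn2 at day 7. Pparg, Lcn2, Il6, Cdkn1a, Hilpda, Fjx1 and Atf4 turned at day 7 without day 7 library 1, and Lcn2 without sham library 3. At day 3 Fasn turned without day 3 library 5, and Lipe without sham library 1, day 3 library 1 or 5 or day 7 library 3.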

Other observations

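In this part the tests of dividing cells and of inherited differences, the counts of other splits of the libraries, and the choice of the lists described here came after the results were seen.

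Immediate early genes, which are transcribed within minutes of a stimulus, rose at day 3 against sham, with 15 of 21 members positive and a median of 0.80 (camera adjusted p = 0.00283; adjusted p = 0.642 with an estimated correlation). Zfp36, a factor that destabilises inflammatory mRNAs, stood at 68.8 ± 28.3 CPM (SD, n = 4) in sham and 190 ± 95.3 CPM (SD, n = 5) at day 3, the transcription factor Klf6 at 112 ± 33.3 and 277 ± 136 CPM, and the phosphatase gene Dusp1 at 56.2 ± 30.0 and 164 ± 81.3 CPM. The heat shock gene Hspa1b went the other way (log2 difference -0.78, SE 0.326), as did Egr3, Nr4a2, Klf2, Hspa1a and Fosb (-1.10, -0.56, -0.45, -0.40 and -0.21). The edgeR adjusted p of the 4 named members was 0.403 to 0.428, and 0 passed, adjusted over the list alone or over all genes tested.

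Genes of the unfolded protein and integrated stress response rose at day 7 against sham, with 20 of 24 members positive and a median of 0.51 (camera adjusted p = 9.3e-04; adjusted p = 0.465 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes tested. This rested on day 7 library 1, whose score was 1.16 against -0.22 and -0.19 in libraries 2 and 3: without it the camera adjusted p was 0.860 and the direction turned. In day 7 libraries 1, 2 and 3, Trib3, a target of ATF4, measured 99.1, 4.83 and 7.81 CPM, the mitochondrial folate enzyme gene Mthfd2 94.4, 14.2 and 17.1 CPM, the chaperone gene Hspa5 2070, 597 and 603 CPM, and Atf4 itself 630, 109 and 116 CPM. The same mouse had the lowest scores of all 12 for mature adipocyte genes (-1.53) and fatty acid and triglyceride synthesis genes (-1.58) and the highest for neutrophil genes (2.47). Phgdh, Pdia4, Hsp90b1 and Pdia6 went against the list (-0.36, -0.31, -0.13 and -0.06).

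Pttg1 lay far below sham in all 5 day 3 libraries, near the sham level in day 7 libraries 1 and 2, and low (6.56 CPM) in day 7 library 3. Fewer dividing cells are argued against as the whole cause. With the cell cycle score as a covariate the log2 difference was -3.35 (SE 0.413), where it had been -3.24 (SE 0.388). The median of the cell cycle list moved from -1.84 to -0.11. That move followed from the adjustment, since the score is the mean of the same list, and it tests nothing. The edgeR adjusted p of Pttg1 went from 0.0253 to 0.0516. The SE was wider and there was 1 residual degree of freedom fewer, whose parts in this were not separated. Of 331 gene to pseudogene pairs, 3 separated every day 3 from every sham library, and in the day 7 libraries the ratios of 2 of these 3 pairs, Ndufs5 and Mid1 with their pseudogenes, took the same sides as Pttg1, while Pisd put all 3 day 7 libraries on the day 3 side, so that 1 of the 3 day 7 libraries took Pttg1's side on every pair. The second count was the first form of the test and was replaced by the count of pairs after it was seen, so an inherited difference between the animals, such as a sub-line of the strain, may lie behind Pttg1 and cannot be told apart from an effect of hepatectomy by these data. An effect at day 3 that has passed by day 7 in some mice stays open, untested.

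Whether chance can be excluded was asked by splitting the same libraries in other ways, with the labelled grouping counted among the splits. For genes at day 3 against sham, 3 of 100 splits gave as many calls (real value 1, highest other 2). That count rests on 1 gene, whose call ended when any 1 sham or day 3 library was left out. Other splits also reached up to 3813 genes at an unadjusted p under 0.05, against 1849 in the labelled grouping. Chance is therefore not excluded for genes at day 3. For genes at day 7 against sham and at day 7 against day 3 the real value was 0, which every split reaches (35 of 35, highest other 1, and 56 of 56, highest other 1878), so these counts decide nothing. The split with 1878 genes set day 3 library 5 with day 7 libraries 2 and 3 against the other day 3 and day 7 libraries. Exchanged labels of day 3 library 5 and day 7 library 1 would give that grouping. As the highest of 56 splits it was singled out after the counts were seen. It does not tell an exchange from other differences among these mice. For lists chance is not excluded in any comparison: 34 of 100 splits gave as many at day 3 (15, highest other 24), 2 of 35 at day 7 (22, highest other 22) and 35 of 56 between the days (14, highest other 26).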
